A study of Saccharomyces cerevisiae W303 with 8 samples.

How the data were processed

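RNA was compared on 2-colour Agilent arrays for 8 samples, 2 strains at 4 time points, with the groups taken from the submitted labels. Per the labels, cells were grown in YPD at 30 degrees C, NaCl was added to 0.4 M, total RNA was extracted with glass beads and phenol, and the sample was labelled with Cy5 and the untreated control strain with Cy3. The labels give each strain and time once, so the 8 groups hold 1 sample each; no dye swap is among the arrays. All 8 arrays lie on a single slide, so slide was no batch to test.

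The deposited scanner files hold, per the file headers, spot and local background intensity in both channels and a log10 ratio of Cy5 over Cy3 that the Agilent software computed from background-subtracted, dye-normalised signals. The deposited 0 or 1 flags mark spots as well above background, saturated or non-uniform, per the file headers. Agilent Feature Extraction 10.5.1.1 made the files, per the headers of 5 files; 3 files hold no settings block and their values are rounded, and for them the version is not given in the sources used here. The deposited value table holds log2 values with the scale, centring and direction unstated by the authors. Set against the scanner values, 5646 of its 5742 complete rows (98.3%) equalled the mean log2 ratio of 1 probe within 0.01 in all 8 columns, which settles scale and direction as log2 of Cy5 over Cy3 with no further centring. Its column medians were -0.00, -0.01, 0.05 and -0.00 in the control strain and 0.01, 0.00, 0.02 and 0.01 in the cdc55 strain at 0, 10, 20 and 30 min. Its row names matched the probe they equalled in 0 cases, so its rows were named through the values, which was possible for 5675 of 6183 rows.

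That comparison also showed that 4 files carry the values of another sample's column: control at 10 min and cdc55 at 0 min were exchanged, and control at 30 min and cdc55 at 20 min were exchanged. With the files as attached, 2 complete rows matched a probe. Each array was assigned to the sample that heads its column in the value table, a departure from the record of files that was decided after seeing the data. The files as attached, and the 4 arrays on which file and column match, were run as alternatives. By this assignment the 3 files with no settings block are both 0 min arrays and the control array at 10 min. File type therefore cannot be told apart from the NaCl response in the cdc55 strain, and only in part in the control strain. Non-uniform Cy5 spots numbered 283 and 267 on the control arrays at 0 and 10 min, and 4 to 28 on the other arrays.

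Median spot and background intensities were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and analysed in R 4.3.3 with limma 3.58.1; figures were drawn with matplotlib 3.10.9. The background was corrected with normexp and an offset of 50, and each array was normalised with loess, with control spots and non-uniform spots at weight 0. Non-uniform spots were left out, no spot was saturated, and the 2 spots of a probe were averaged. Of 6256 probes 12 had no usable spot on 1 or more arrays and 136 were well above background in Cy5 on fewer than 3 of 8 arrays, which left 6108. Gene names come from the array's systematic names, of which 5740 of 6228 were in the given RefSeq gene table of the S288C genome and 488 were not and kept the name in the file. That table's assembly differs from the build named in the file headers, so no coordinates are printed. A gene with several probes, of which there were 26, is represented by its brightest probe.

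The median Cy5 signal of an array lay between 5523 and 13697 over a median background of 44 to 54. The model had a term for each time point and a strain term that differed between unstressed and stressed arrays: 6 coefficients for 8 arrays, 2 residual degrees of freedom, and 3.93 prior degrees of freedom from eBayes. The spread therefore comes from how the strain difference varied over 10, 20 and 30 min, and the arrays at 0 min are assumed to vary alike. P-values were adjusted by the Benjamini-Hochberg method over all probes, with a threshold of 0.05. Unless stated, changes are given as log2 with the standard error of the moderated fit.

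Before the data were examined, 26 gene lists, the contrasts, the alternatives and the rule for named genes were fixed from general knowledge. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 26 lists of a contrast; members were also adjusted over the list alone. The result of 1 of these lists is not reported here. No list passed with an estimated correlation in any contrast, where the smallest adjusted p was 0.502. That correlation was estimated from 2 residual degrees of freedom, and in the simulation below this test also missed a shifted list (adjusted p = 0.0659). Its lack of passes here and below is therefore weak evidence against a list, and lends no weight to the preset correlation. The named genes are, for each of the first 5 contrasts, the 10 largest positive and 10 largest negative changes among genes past the threshold with the same sign at all 3 NaCl times (the unstressed contrast has no sign rule), or the 5 each way with the smallest p where none passed; up to 4 members with the largest change of each list described; and MSN2, MSN4, CDC55, the marker genes, CTT1, HSP12, ALD3, PGM2, DDR2, GPD1, GPP2, STL1, GRE2 and ENA1.

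The steps were tested on simulated data for 6108 probes, with 67, 67 and 66 of them changed by 0.5, 1 and 2 on the log2 scale. For the strain effect in stressed cells 4.48%, 77.6% and 95.5% of probes changed by 0.5, 1 and 2 were called; for the difference in response 0%, 0% and 36.4%; for unstressed cells 0%, 2.99% and 65.2%; for the control response 0%, 1.49% and 90.9%; and for the cdc55 response 0%, 7.46% and 97.0%. A simulated list shift in stressed cells had an adjusted p of 4.43e-55 with the preset correlation, 0.0659 with an estimated one and 0.00243 with fry, and 1, 0 and 0 of 25 unshifted lists passed. The simulated strain shifts were the same at 10, 20 and 30 min. The real strain difference of the Msn2 list was -0.22, -0.70 and -0.90 at these times. For strain differences that change with time the shares called may therefore be too high. The simulated noise was independent between probes. In the real data the estimated correlation was 0.63 in the Msn2 list and 0.87 in the ribosome assembly list. The simulation therefore cannot show how often an unshifted list passes with the preset correlation on these arrays.

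Alternatives were other background corrections, median centring, a further Aquantile step, the Agilent log ratio, the value table, other filters on dim probes, an additive strain term, cell means with no time term, an intensity trend with robust eBayes, each NaCl time left out in turn, and an estimated correlation. A list of genes with stress response elements in their promoters, planned for 2 promoter lengths, needs a genome sequence and was not analysed here.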

Results

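Gene expression was measured in budding yeast (Saccharomyces cerevisiae, W303 background) before and after hyperosmotic stress with 0.4 M NaCl. Per the labels, both strains lacked the chromosomal MSN2 and MSN4 genes, which encode related stress transcription factors, and carried a plasmid that the labels call pMsn2pMsn2DNES. The strain called cdc55 here is labelled as also lacking CDC55, which encodes a regulatory B subunit of the protein phosphatase PP2A. The other is called the control strain. The series title asks how PP2A with Cdc55 acts on the transcriptional response to hyperosmolarity through Msn2 and Msn4. Each strain was sampled at 0, 10, 20 and 30 min, with 1 array per strain and time and no replicate arrays. The sample was labelled with Cy5 and a common reference, RNA of the untreated control strain, with Cy3. A positive log2 ratio therefore means more RNA in the sample than in that reference. All p-values measure only how these arrays varied around the model, mainly how the strain difference varied over the 3 times with NaCl. They hold no spread between repeated cultures.

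Each array carried 6256 probes in 2 spots each, and between 93.1% and 98.6% of the spots of an array were well above background in Cy5. The control strain at 0 min, hybridised against RNA of the same strain, gave log2 ratios with an SD of 0.15 over 6108 probes, and 1 probe differed by more than 2-fold. On the cdc55 array at 0 min 140 probes differed by more than 2-fold from the reference, and on the 6 arrays with NaCl between 592 and 1141 did. The deposited sources disagreed on which array belonged to which sample. The scanner files attached to the control strain at 10 min and the cdc55 strain at 0 min held the values of each other's column in the deposited value table. The files attached to the control strain at 30 min and the cdc55 strain at 20 min were exchanged in the same way, so that 4 of 8 files were affected. The values given here follow the columns of the value table, a choice made after the data were seen. Every comparison below is also given with the files as attached.

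CDC55 itself had lower values in the cdc55 strain at all 4 time points. Its log2 ratio was 0.15, 0.17, 0.14 and 0.45 in the control strain at 0, 10, 20 and 30 min, and -0.51, -0.21, -0.44 and -0.54 in the cdc55 strain. The means were 0.23 ± 0.15 (SD, n = 4 arrays) and -0.42 ± 0.15 (SD, n = 4 arrays). In stressed cells the difference of -0.65 ± 0.16 (SE) did not pass the test (limma adjusted p = 0.0883). It passed without the 10 min arrays (adjusted p = 0.0129), with a strain term held constant over time (adjusted p = 0.0207) and with an intensity trend in the variance (adjusted p = 0.0202). Here and below, a pass without the 10 min arrays is weak evidence. The spread then rests only on how the strain difference varied between 20 and 30 min. Calls in stressed cells rose from 135 to 1012 with that step. The CDC55 probe stayed well above background on all 8 arrays. Whether it lies inside the deleted part of the gene is not given in the sources used here, so it is a weak check of the genotype. With the files as attached CDC55 was lower in the cdc55 strain at 1 of 4 time points.

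MSN2, which the labels place on the plasmid in both strains, had a log2 Cy5 signal of only 6.84 to 7.40. It was well above background in Cy5 on 6 of 8 arrays but in Cy3 on 2 of 8, so its ratios are not given. The MSN4 probe, in strains labelled as lacking MSN4, had a log2 Cy5 signal of 13.11 to 14.28 and was well above background in both channels on all 8 arrays. Both levels run against the labels taken at face value. Whether the MSN2 probe lies in the part carried by the plasmid, and the MSN4 probe in the deleted part, is not given in the sources used here. The MSN4 signal rose with NaCl by 1.08 ± 0.19 in the control strain (limma adjusted p = 0.0244). In the cdc55 strain it rose by 1.04 ± 0.19 (adjusted p = 0.0434). Both calls were lost without the 20 min arrays (adjusted p = 0.158 and 0.245). Genes often used as strain markers also differed between the strains. ADE2, an adenine synthesis gene, was higher in stressed cdc55 cells by 2.38 ± 0.22 (adjusted p = 0.0106). CAN1, the arginine permease gene, was higher by 0.84 ± 0.12 (adjusted p = 0.0366). MET17, a sulfhydrylase gene of sulfur assimilation, was lower, at -2.19 ± 0.14 (adjusted p = 0.00466). HIS3 at -0.70 ± 0.14 and LYS2 at -0.69 ± 0.14 did not pass (adjusted p = 0.0602 and 0.0637), but passed without the 10 min arrays (adjusted p = 0.0289 and 0.00986). LEU2, URA3 and TRP1 did not pass. Among the 11 genes of the list of engineered and marker genes 2 were higher, 1 was lower and 8 did not pass, and adjusted over the list alone 2 were higher and 4 lower.

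**Figure D1:**
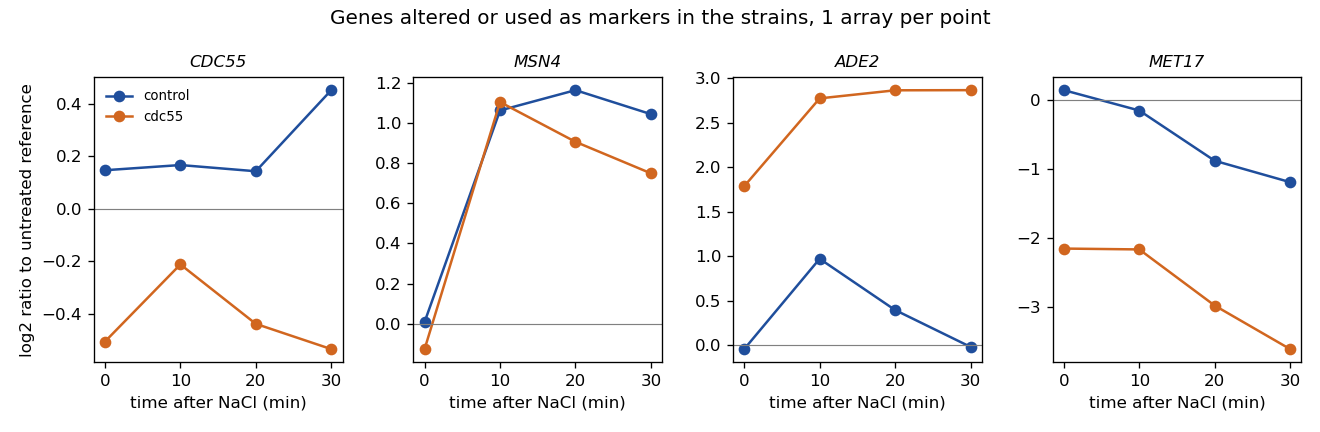
Log2 ratio to the untreated reference (y axis) against time after NaCl in min (x axis) for CDC55, MSN4, ADE2 and MET17, with 1 array per point and 1 line per strain (blue, control; orange, cdc55). CDC55 lies below the control line at 4 of 4 times, and ADE2 lies between 1.79 and 2.86 in the cdc55 strain.

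The first comparison asked how the control strain responded to NaCl, as the mean of 10, 20 and 30 min against 0 min. Among the genes that rose most, CTT1, the cytosolic catalase T gene, rose by 6.92 ± 0.36 (log2, SE; limma adjusted p = 9.38e-04), and HSP12, a small heat shock protein gene, by 6.61 ± 0.31. STL1, the glycerol symporter gene, rose by 5.94 ± 0.35, GPP2, a glycerol phosphatase gene, by 5.86 ± 0.23, and GPD1, which encodes glycerol 3-phosphate dehydrogenase, by 5.12 ± 0.22. RTC3, ALD3, NQM1, GRE2 and PHM7 rose by 6.82, 5.93, 5.27, 5.25 and 5.09. ENA1, a sodium pump gene, rose by 2.31 ± 0.40, DDR2 by 2.83 ± 0.51 and the phosphoglucomutase gene PGM2 by 2.46 ± 0.42. Among the genes that fell most were PHM6, a phosphate-regulated gene, at -3.80 ± 0.19, and the purine salvage genes AAH1 and HPT1 at -3.17 and -3.16. The ribosome assembly genes SPB1, RRP12, SYO1 and ARX1 were at -2.95, -2.94, -2.83 and -2.69, SFG1 at -2.96, HO at -2.79 and the phosphate transporter gene PHO84 at -2.66. In all, 828 of 6108 probes passed, 468 higher and 360 lower, and 823 of them had the same sign at all 3 times.

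Of the 55 genes known to be driven by Msn2 and Msn4 through stress response elements, 43 rose, 0 fell and 12 did not pass, and 48 rose when adjusted over the list alone. The list had a median change of 1.96 (SD over members 1.61; camera adjusted p = 1.45e-23, and adjusted p = 0.554 with an estimated correlation). Of 16 osmostress genes known to depend on Hog1 through Hot1, Sko1 or Smp1, 10 rose, 1 fell, which was PHO84, and 5 did not pass. Adjusted over the list alone 13 rose and 1 fell. Their median was 1.81 (camera adjusted p = 6.42e-09, and adjusted p = 0.554 with an estimated correlation). The fry test, which asks whether a list moves in one direction on balance, gave an adjusted p of 0.0396 for these Hog1-dependent genes, the only 1 of 26 lists to pass it. The Msn2, glycerol, trehalose and ribosome assembly lists did not (fry adjusted p = 0.121, 0.109, 0.191 and 0.191). Of 13 glycerol genes 7 rose and 6 did not pass, and 8 rose and 1 fell adjusted over the list alone. Of 21 trehalose and glycogen genes 11 rose and 10 did not pass, and 14 rose adjusted over the list alone. TPS2, the trehalose phosphatase gene, rose by 3.46 ± 0.24 and TSL1, a trehalose synthase subunit gene, by 2.22 ± 0.35. The medians of the glycerol and trehalose lists were 1.89 and 0.75 (camera adjusted p = 2.45e-05 and 1.04e-06), each with adjusted p = 0.554 with an estimated correlation.

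All 56 ribosome assembly genes had negative changes in the control strain, with a median of -1.95. Of these 34 fell and 22 did not pass, and 55 fell adjusted over the list alone (camera adjusted p = 2.39e-19, and adjusted p = 0.554 with an estimated correlation). DBP3 fell by 2.52 ± 0.44 and NOC2 was at -2.45 ± 0.50. Of 131 cytosolic ribosomal protein genes 7 fell, 1 rose and 123 did not pass, with 0 past the test adjusted over the list alone. Their median was -0.43 (camera adjusted p = 3.31e-10, and adjusted p = 0.554 with an estimated correlation).

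In the control strain 33 probes passed without the 20 min arrays and 1750 without the 10 min arrays, and with the files as attached limma called 0 (304 at an unadjusted p under 0.05). Median centring of each array in place of loess gave 539 probes higher and 659 lower, and leaving out 20 min ended the calls of PHM7, AAH1, HPT1, SFG1, SPB1, RRP12, SYO1, HO, ARX1, PHO84, PGM2, DDR2 and ENA1 (adjusted p from 0.0513 for SFG1 to 0.277 for SYO1), while an intensity trend in the variance ended those of PHM6 (adjusted p = 0.0883), AAH1, SFG1, HO and PHO84.

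The cdc55 strain was then compared with its own 0 min array in the same way. GPP2 rose by 6.66 ± 0.23 (log2, SE; limma adjusted p = 4.21e-04), HSP12 by 6.49 ± 0.31, RTC3 by 6.35 ± 0.19, CTT1 by 6.14 ± 0.36 and STL1 by 5.76 ± 0.35. NQM1, ALD3, GPD1, FMP48 and GRE2 rose by 5.13, 4.92, 4.85, 3.98 and 3.97. Among the genes that fell, HO was at -3.15 ± 0.34, AAH1 at -2.73 ± 0.50, HMS1 at -2.69 ± 0.24, INA1 at -2.41 ± 0.35 and HAP4, a regulator of respiratory genes, at -2.32 ± 0.23. FAR1, an inhibitor of the G1 cyclin kinase, was at -2.27 ± 0.24, and FRE7, LEU9, CTR1 and YDL241W were at -2.07, -2.06, -2.00 and -1.95. ENA1 rose by 2.25 ± 0.40 (adjusted p = 0.0429). PGM2 and DDR2 had changes of 0.89 ± 0.42 (adjusted p = 0.235) and 1.71 ± 0.51 (adjusted p = 0.114) and did not pass, though both did without the 10 min arrays (adjusted p = 0.0270 and 0.00126). In all, 256 probes passed, 176 higher and 80 lower.

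In the cdc55 strain 21 of the 55 Msn2 genes rose, 0 fell and 34 did not pass, and 40 rose adjusted over the list alone. Their median was 1.12 (SD over members 1.49; camera adjusted p = 4.04e-19, and adjusted p = 0.665 with an estimated correlation). Of the 16 Hog1-dependent genes 8 rose and 8 did not pass, and 12 rose and 1 fell adjusted over the list alone. Their median was 1.63 (camera adjusted p = 3.18e-10, adjusted p = 0.665 with an estimated correlation, fry adjusted p = 0.0418). Of 13 glycerol genes 5 rose and 8 did not pass, and 6 rose adjusted over the list alone, with a median of 1.25 (camera adjusted p = 1.17e-05, and adjusted p = 0.665 with an estimated correlation). Of 21 trehalose and glycogen genes TPS2 rose by 2.63 ± 0.24 and TSL1 by 2.13 ± 0.35, and 19 did not pass, with 9 higher adjusted over the list alone. That list had a median of 0.60 (camera adjusted p = 1.39e-04, and adjusted p = 0.667 with an estimated correlation). The 56 ribosome assembly genes had a median of -1.49, with 0 past the test over all probes and 50 lower adjusted over the list alone (camera adjusted p = 1.30e-18, and adjusted p = 0.665 with an estimated correlation). The Hog1-dependent list was the only 1 of 26 to pass fry, and the Msn2, glycerol, trehalose and ribosome assembly lists did not (fry adjusted p = 0.221, 0.115, 0.261 and 0.261).

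Of the 468 probes called higher in the control strain and the 176 in the cdc55 strain 170 were shared. Of the 360 and 80 called lower 66 were shared. Each strain's response used its own 0 min array, so the responses had no array in common, but all arrays shared the reference and both tests the same standard error per gene, so the lists of calls are not independent. Across the 6108 probes, which are not independent replicates, the responses correlated with r = 0.942. In the cdc55 strain 13 probes passed without the 20 min arrays, 961 without 10 min and 924 without 30 min, and FMP48, ENA1, MSN4 and the genes named as lower lost their calls without 20 min, and the latter also with an intensity trend in the variance (adjusted p from 0.0753 for HMS1 to 0.145 for CTR1). Median centring gave 273 higher and 273 lower, and with the files as attached limma called 0 (229 at an unadjusted p under 0.05) and the median of the Msn2 list turned to -0.12.

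**Figure D2:**
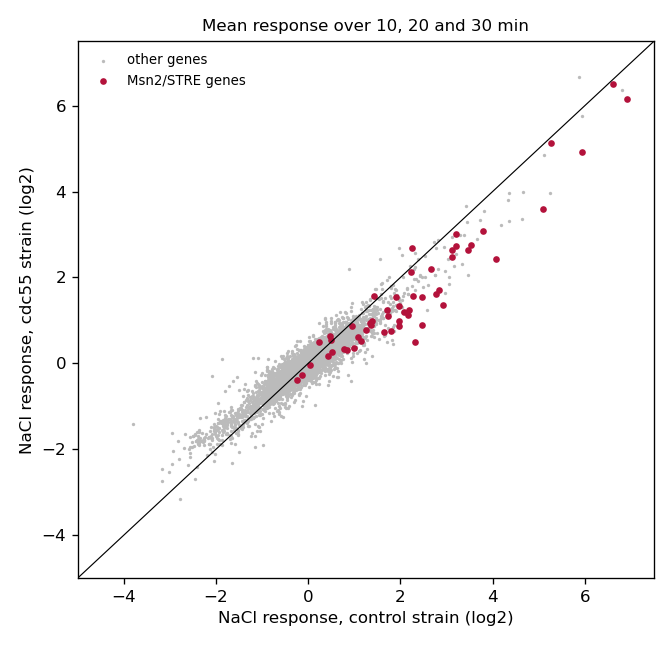
Mean NaCl response over 10, 20 and 30 min in the cdc55 strain (y axis, log2) against that in the control strain (x axis, log2), with 1 point per gene, Msn2 genes in red and other genes in grey; the line marks equal responses. Of the red points 50 of 55 lie under the line, and the median of the Msn2 genes is 1.12 on the y axis and 1.96 on the x axis.

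Whether the response itself differed between the strains was tested as the difference of both responses, cdc55 minus control. As a group the Msn2 genes had smaller responses in the cdc55 strain, with a median difference of -0.48 (SD over members 0.50) and negative values for 50 of 55 genes. The shift had a camera adjusted p of 7.17e-22, and adjusted p = 0.742 with an estimated correlation, and 0 genes passed singly in limma, over all probes or adjusted over the list alone. The fry test gave an adjusted p of 0.982 for this list, and 0 of 26 lists passed it (smallest adjusted p = 0.924). RTN2 differed by -1.82 ± 0.57, MSC1 by -1.65 ± 0.42, PGM2 by -1.57 ± 0.59 and SOL4 by -1.56 ± 0.43. The strain difference of the Msn2 list had a median of 0.04 at 0 min, -0.22 at 10 min, -0.70 at 20 min and -0.90 at 30 min, with 25, 37, 52 and 51 of 55 genes lower in the cdc55 strain. At 20 and 30 min PGM2 was at 2.92 and 3.03 in the control strain and at 1.27 and 0.87 in the cdc55 strain. CTT1 differed between the strains by -0.37 at 20 min and -1.23 at 30 min. The Hog1-dependent list differed by 0.23, 0.33, 0.16 and -0.14 at the same 4 times. With each strain's 0 min array subtracted its median response was 1.96, 2.08 and 1.96 at 10, 20 and 30 min in the control strain and 2.31, 1.74 and 0.95 in the cdc55 strain, weaker there in 7, 11 and 10 of 16 genes. Its median difference in response was -0.18, with 11 of 16 genes negative, 0 past the test and 1 lower adjusted over the list alone (camera adjusted p = 0.0482, and adjusted p = 0.785 with an estimated correlation).

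Ribosome assembly genes differed between the strains by a median of 0.45, 0.06, 1.09 and 1.62 at 0, 10, 20 and 30 min, and 56 of 56 were higher in the cdc55 strain at 30 min. Their median difference in response was 0.44, positive in 55 of 56 genes, with 0 past the test or adjusted over the list alone (camera adjusted p = 2.18e-07, and adjusted p = 0.792 with an estimated correlation). Without the 30 min arrays it was 0.10 (camera adjusted p = 0.615). Phosphate starvation genes, known targets of Pho4, had a median difference in response of 0.83, positive in 15 of 16 genes, with 0 past the test and 1 adjusted over the list alone (camera adjusted p = 3.81e-13, and adjusted p = 0.634 with an estimated correlation). Among the genes with the smallest p-values PHM6 differed by 2.39 ± 0.26 (limma adjusted p = 0.654), SPL2 by 1.98 ± 0.51, GAP1, an amino acid permease gene, by 1.79 ± 0.30, and MET5 by 1.32 ± 0.32. For PHM6 too the control response was a fall, at -3.80, and the strain difference at 0 min was -3.05. GRE2 differed by -1.28 ± 0.24, SDP1 by -1.27 ± 0.26 and GSY1, a glycogen synthase gene, by -1.11 ± 0.24. None of these passed on all arrays, but PHM6 and SPL2 did without the 10 min arrays (adjusted p = 0.0197 and 0.0221).

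Over all probes limma called 0 of 6108 in this test of the difference. At an unadjusted p under 0.05 there were 81, less than a share of 0.05 of the probes. In the simulation this test called 0% of probes changed by 1 and 36.4% of those changed by 2. Its lack of calls therefore says little about smaller differences. Without the 10 min arrays it called 2, PHM6 and SPL2, and the median of the Msn2 list was -0.74. With the files as attached 0 passed (20 at an unadjusted p under 0.05) and that median was -1.28.

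**Figure D3:**
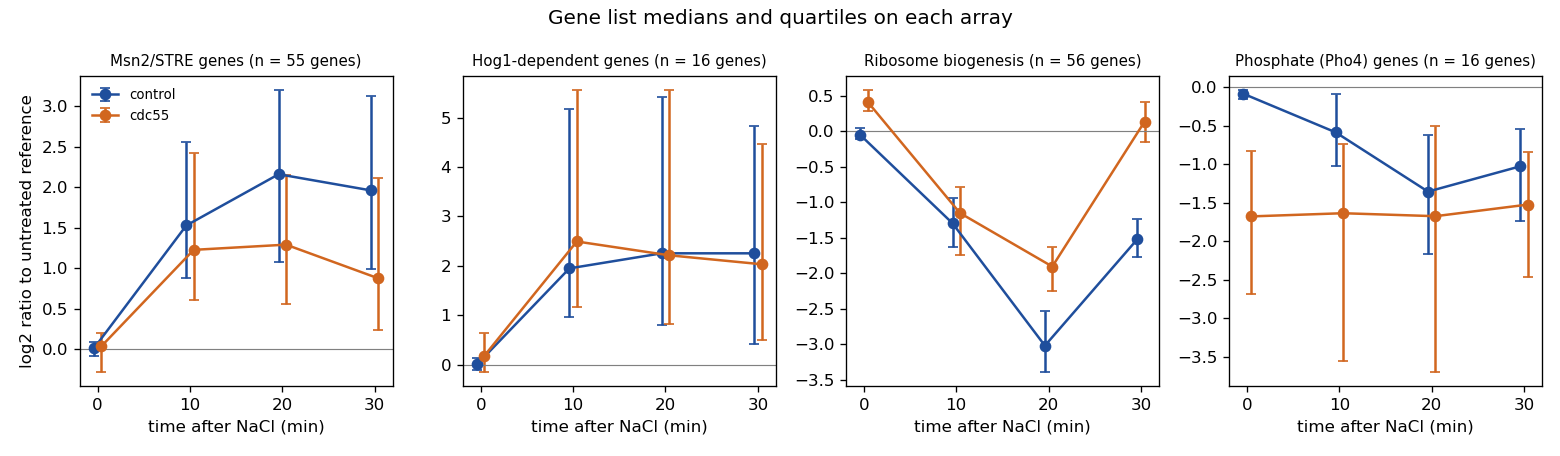
Median and quartiles over list members of the log2 ratio to the untreated reference (y axis) against time after NaCl in min (x axis) for Msn2 genes (n = 55), Hog1-dependent genes (n = 16), ribosome assembly genes (n = 56) and phosphate genes (n = 16), blue for control and orange for cdc55, 1 array per point. The median of the Msn2 genes is 1.96 in the control strain and 0.87 in the cdc55 strain at 30 min.

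**Figure D4:**
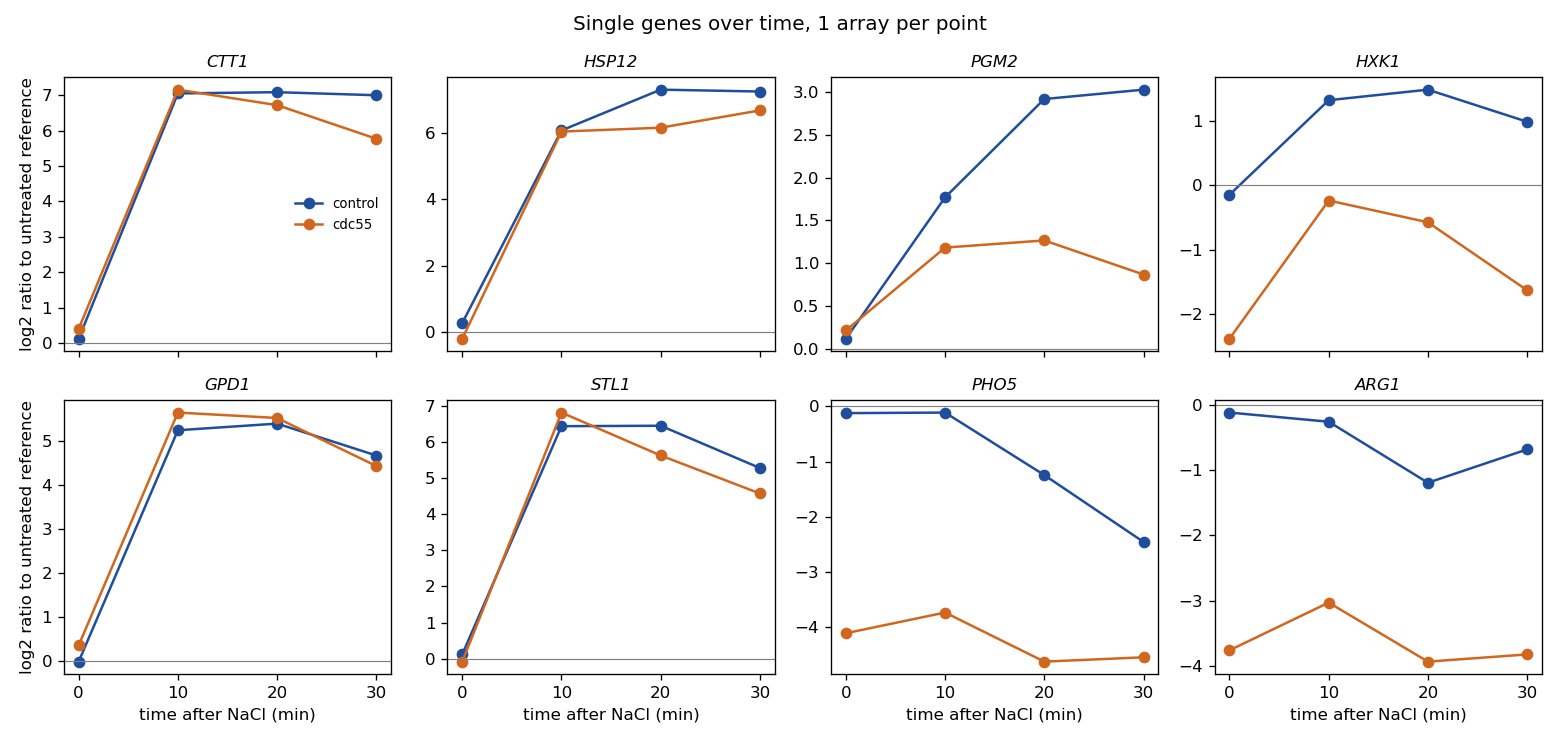
Log2 ratio to the untreated reference (y axis) against time after NaCl in min (x axis) for CTT1, HSP12, PGM2, HXK1, GPD1, STL1, PHO5 and ARG1, with 1 array per point, blue for control and orange for cdc55. HXK1, PHO5 and ARG1 differ by -2.24, -4.00 and -3.64 at 0 min, while CTT1 and PGM2 differ by 0.28 and 0.10 there.

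The strains were also compared within stressed cells, as cdc55 minus control averaged over 10, 20 and 30 min. PHO5, the secreted acid phosphatase gene, was lower in the cdc55 strain at -3.04 ± 0.30 (log2, SE; limma adjusted p = 0.0149), and ARG1, the argininosuccinate synthetase gene, at -2.89 ± 0.14 (adjusted p = 0.00466). The iron oxidase gene FET3 was at -2.24 ± 0.18, MET17 at -2.19 ± 0.14, the ergosterol synthesis gene ERG27 at -2.13 ± 0.27 and the hexokinase gene HXK1 at -2.08 ± 0.21. DUG1, CPR5 and YCL021W-A were lower too, at -2.48, -2.47 and -2.38. PHO11, whose probe may share signal with the near-identical PHO5 and PHO12, was at -2.05 ± 0.32. PRM7 was higher by 2.72 ± 0.26, ADE2 by 2.38 ± 0.22, BSC1 by 2.14 ± 0.23, YOR338W by 1.77 ± 0.27 and the polyamine transporter gene TPO2 by 1.52 ± 0.22. SET6, SPO22, YFL051C, RLI1 and YRO2 were higher by 1.45, 1.29, 1.15, 1.09 and 1.01. In all, 135 probes passed, 22 higher and 113 lower, each with the same sign at all 3 times.

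Of the 55 Msn2 genes 6 were lower, 0 higher and 49 did not pass in this contrast, and 31 were lower and 1 higher adjusted over the list alone. Their median was -0.64 (SD over members 0.51; camera adjusted p = 7.85e-13, and adjusted p = 0.502 with an estimated correlation). Among the lower ones were HXK1, RTN2 at -1.67 ± 0.28 and ALD3 at -0.95 ± 0.15 (limma adjusted p = 0.0428). HXK1 was about as much lower before NaCl, as given below, so its difference is no sign of a weaker response. PGM2 at -1.47 ± 0.29 (adjusted p = 0.0635), CTT1 at -0.50 ± 0.26 and HSP12 at -0.58 ± 0.22 did not pass, though all of them did without the 10 min arrays (-1.91, -0.80 and -0.86). Of 21 trehalose and glycogen genes 3 were lower and 18 did not pass, and 13 were lower adjusted over the list alone. GSY1 was at -1.93 ± 0.12 and GPH1, the glycogen phosphorylase gene, at -1.02 ± 0.13, and the list had a median of -0.61 (camera adjusted p = 1.49e-08, and adjusted p = 0.502 with an estimated correlation).

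Of the 16 Hog1-dependent genes 0 passed in stressed cells in limma, over all probes or adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.335, and adjusted p = 0.814 with an estimated correlation). That median was -0.03 without the 10 min arrays. GPD1, GPP2, STL1 and GRE2 differed by 0.10, 0.21, -0.38 and 0.23, and STL1 passed without the 10 min arrays at -0.76. Of 13 glycerol genes GCY1 was lower at -1.23 ± 0.14 and 12 did not pass, with 1 lower adjusted over the list alone. The glycerol list had a median of 0.07 but a mean of -0.24 (camera adjusted p = 0.722, and adjusted p = 0.947 with an estimated correlation).

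Of 40 amino acid synthesis genes known as Gcn4 targets 7 were lower and 33 did not pass, and 21 were lower adjusted over the list alone, for example LYS9 at -2.00 ± 0.13 and ARG3 at -1.82 ± 0.16. Of 22 sulfur and methionine genes 4 were lower and 18 did not pass, and 13 were lower adjusted over the list alone, for example MET6 at -1.75 ± 0.20 and MET10 at -1.49 ± 0.17. Of 16 phosphate genes PHO5 and PHO11 were lower and 14 did not pass, and 6 were lower adjusted over the list alone. All 44 genes of respiration and the citric acid cycle had negative values. Of these 3 were lower, with HAP4 at -1.11 ± 0.16 and COX4 at -0.94 ± 0.14, 41 did not pass, and 28 were lower adjusted over the list alone. The medians of these 4 lists were -0.47, -0.60, -0.57 and -0.50 (camera adjusted p = 6.68e-12, 2.44e-08, 5.41e-05 and 5.58e-14), each with adjusted p = 0.502 with an estimated correlation. Ribosome assembly genes had a median of 0.87, positive in 56 of 56, with 0 past the test and 29 higher adjusted over the list alone (camera adjusted p = 2.07e-16, and adjusted p = 0.502 with an estimated correlation). Ribosomal protein genes had a median of 0.29, positive in 124 of 131 (camera adjusted p = 6.04e-14, and adjusted p = 0.502 with an estimated correlation). RPL22B was higher by 0.78 ± 0.13 and the other 130 did not pass, with 0 past the test adjusted over the list alone. The fry test passed for 1 of 26 lists in stressed cells, the mating type list, and not for the Msn2, Gcn4, respiration or ribosome assembly lists (fry adjusted p = 0.207, 0.168, 0.168 and 0.304).

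Without the 20 min arrays limma called 0 probes in stressed cells (678 at an unadjusted p under 0.05), without 10 min 1012, and without 30 min 29, when PRM7, BSC1, YOR338W, TPO2, SET6, YFL051C, RLI1, YRO2, CAN1 and ALD3 lost their calls; TPO2 and ALD3 also lost theirs with the Agilent log ratio (adjusted p = 0.0536 and 0.0647), and an intensity trend in the variance ended those of PHO5, PHO11 and ALD3 (adjusted p = 0.0504, 0.148 and 0.119). With the files as attached 0 passed (18 at an unadjusted p under 0.05) and the median of the Msn2 list turned to 0.37, and median centring gave 144 higher and 257 lower.

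The strains were last compared before NaCl, at 0 min, with 1 array each. ARG1 was lower in the cdc55 strain at -3.64 ± 0.24 (log2, SE; limma adjusted p = 0.0268), as were PHM6 at -3.05 ± 0.23 and YCL021W-A at -3.01 ± 0.23. These were the 3 probes that passed. PHO5 at -4.00 ± 0.52 (adjusted p = 0.129), SPL2 at -3.22 ± 0.44, FET3 at -2.49 ± 0.32, MET17 at -2.31 ± 0.24 (adjusted p = 0.0748) and HXK1 at -2.24 ± 0.37 did not pass. All 16 phosphate genes had negative values with a median of -1.54, 1 was lower and 15 did not pass, and 10 were lower adjusted over the list alone. All 22 sulfur and methionine genes had negative values with a median of -0.97, 0 past the test and 10 lower adjusted over the list alone. Of 40 Gcn4 targets 39 had negative values, with a median of -0.69, 1 lower and 39 not past the test, and 10 lower adjusted over the list alone. The camera adjusted p of these 3 lists were 3.95e-15, 1.29e-13 and 7.79e-20, each with adjusted p = 0.620 with an estimated correlation.

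Respiration genes at 0 min had a median of -0.50, negative in 44 of 44, with 0 past the test or adjusted over the list alone (camera adjusted p = 4.92e-15, and adjusted p = 0.620 with an estimated correlation). Higher in the cdc55 strain were the ribosome assembly (median 0.45), proteasome (0.36), ribosomal protein (0.13) and Hog1-dependent lists (0.23). Their camera adjusted p were 3.06e-06, 1.62e-07, 0.00444 and 0.0377, and 0.805, 0.754, 0.805 and 0.754 with an estimated correlation. The trehalose list was lower, at -0.21 (camera adjusted p = 0.0129, and adjusted p = 0.805 with an estimated correlation). The Msn2 list had a median of 0.04 and a mean of -0.04, with 30 genes positive and 25 negative and 0 past the test or adjusted over the list alone (camera adjusted p = 0.868, and adjusted p = 0.975 with an estimated correlation). At 0 min 0 of 26 lists passed fry (smallest adjusted p = 0.293). Of the 113 probes called lower in stressed cdc55 cells 109 were also lower at 0 min, and of the 22 called higher 22 were also higher. Over all 6108 probes, which are not independent replicates, the differences before and after NaCl correlated with r = 0.760. Without the 20 min arrays limma called 0 probes at 0 min (231 at an unadjusted p under 0.05), without 10 min 72, and without 30 min PHM6 and YCL021W-A lost their calls (adjusted p = 0.0771 for both). With the files as attached, with no time term or with an intensity trend in the variance 0 passed (97, 177 and 426 at an unadjusted p under 0.05), and median centring gave 2 higher and 18 lower.

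Over both strains together 30 min was set against 10 min. MMP1, a methylmethionine permease gene, was lower late at -1.66 ± 0.14 (log2, SE; limma adjusted p = 0.0111) and MUP1, a methionine permease gene, at -1.80 ± 0.38. Of 22 sulfur and methionine genes 6 were lower and 16 did not pass, and 9 were lower adjusted over the list alone (median -0.57, camera adjusted p = 4.98e-04, and adjusted p = 0.834 with an estimated correlation). Of 24 hexose transporter and sugar genes 4 were lower, among them HXT2 at -2.24 ± 0.15, HXT4 at -1.93 ± 0.23 and HXT1 at -1.50 ± 0.24, MIG2 was higher and 19 did not pass. Adjusted over the list alone 12 were lower and 1 higher (median -0.53, camera adjusted p = 0.00189, and adjusted p = 0.834 with an estimated correlation). Of 24 ergosterol genes 4 were lower, with UPC2, a regulator of sterol synthesis, at -1.76 ± 0.29, 20 did not pass, and 7 were lower adjusted over the list alone (median -0.30, camera adjusted p = 0.00290, and adjusted p = 0.834 with an estimated correlation). The Hog1-dependent genes went both ways, with 2 higher, 5 lower and 9 not past the test, and 2 higher and 7 lower adjusted over the list alone (median -0.18, camera adjusted p = 0.222, and adjusted p = 0.834 with an estimated correlation). STL1 was at -1.70 ± 0.31 and PHO84 was higher by 2.83 ± 0.53. The 32 proteasome genes were positive in 31, with a median of 0.49 and 0 past the test (camera adjusted p = 2.32e-05, and adjusted p = 0.834 with an estimated correlation). Of 56 ribosome assembly genes 3 were higher and 53 did not pass (median 0.50, camera adjusted p = 0.00189, and adjusted p = 0.834 with an estimated correlation). Their median response at 10 and 30 min was -1.24 and -1.47 in the control strain, and -1.56 and -0.28 in the cdc55 strain. The strains were not alike in the sulfur and proteasome lists either. The sulfur list had -0.32 and -0.50 in the control strain, and 0.19 and -0.61 in the cdc55 strain. The proteasome list had 0.22 and 0.96 in the control strain, and 0.35 and 0.54 in the cdc55 strain. For late against early 0 of 26 lists passed fry (smallest adjusted p = 0.0877). In all, 474 probes passed, 205 higher and 269 lower. Without the 20 min arrays 7 did, and with the files as attached limma called 0 (272 at an unadjusted p under 0.05).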

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

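The tests of explanations in this part were chosen after the result was seen, except the test on adenine synthesis genes and the count of sample splits, while the limma test of LYS20 and the camera test of the pheromone list were planned. In the tests of explanations ± is the standard error of a median, from resampling the genes. It treats genes that move together as independent and holds no spread between arrays or cultures. Where an explanation is argued against, that is so for these arrays only.

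LYS20, a lysine synthesis gene, differed in its mean NaCl response by -1.12, cdc55 minus control, and was picked out because all 3 responses were positive in the control strain and negative in the cdc55 strain. The limma test of this difference gave a p of 0.00363 before adjustment and did not pass after it. The control values at 10, 20 and 30 min were 0.34, -0.03 and -0.02 against -0.05 at 0 min, so the sign at 20 and 30 min rests on values close to 0. The mean of the median responses of the 28 pheromone and filamentation genes differed by -0.20, cdc55 minus control, and was picked out in the same way, being positive at each NaCl time in the control strain and negative in the cdc55 strain. The control medians were 0.15, 0.0095 and 0.0025 at 10, 20 and 30 min, so the sign at 20 and 30 min rests on values close to 0 as well. The camera test of that list's difference in response gave an adjusted p of 8.40e-07, and adjusted p = 0.634 with an estimated correlation.

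Phosphate, amino acid and sulfur genes had lower values in unstressed cdc55 cells than in control cells. A fault of the 0 min array alone is argued against for these genes pooled, since their median difference was -0.37 ± 0.08 (SE over 78 genes) even at 20 min, where it was nearest to 0. The phosphate list alone had -1.54 at 0 min and -1.05, -0.24 and -0.39 at 10, 20 and 30 min. Most of its shift was thus gone by 20 min, and for the phosphate genes the pooled value does not carry the argument. An effect of the ADE2 difference on purine intermediates could be another source, but the other 11 adenine synthesis genes had a median difference of 0.044 ± 0.19, too wide a spread to decide. With 1 time course of the cdc55 strain, a difference of those cultures in genotype, growth stage or medium other than CDC55 stays open as well. The loss of CDC55 itself is a hypothesis that the design names and that these arrays cannot separate from the last.

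The Msn2 genes had a weaker late response in the cdc55 strain. Compression of large ratios on its arrays as the whole cause is argued against, since the Hog1-dependent list differed by a median of -0.025 ± 0.16 over 20 and 30 min while the Msn2 list differed by -0.86 ± 0.09; with each strain's 0 min array subtracted the values were -0.30 ± 0.20 and -0.74 ± 0.09, so a part stays open. A fault of the 30 min array alone is argued against by the -0.70 ± 0.11 of the Msn2 list at 20 min. An earlier recovery of the whole response may account for it: of the 751 probes called in the control strain outside the Msn2 and ribosome assembly lists 88.7% responded less in the cdc55 strain at 30 min, against 54.3% at 10 min. Probes picked by their control response tend to be larger there, and among the 235 called in the cdc55 strain the shares were 71.1% and 35.3%, so a loss of Msn2 activity in particular stays a hypothesis. The 751 may also hold Msn2 targets outside the list of 55, so these shares cannot separate both readings. Nor did every list recover earlier. At 30 min ribosome assembly genes had a median response of -0.28 in the cdc55 strain against -1.47 in the control strain. The G1 to S genes fell further, at -0.92 against -0.41, with 23 of 29 lower in the cdc55 strain.

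For the exchanged scanner files, interchanged columns of the value table are argued against in both pairs. In the first pair the file attached to the control strain at 10 min of NaCl had a median log2 ratio of 0.035 ± 0.056 for the Msn2 genes, a list raised at every NaCl time under the columns' assignment. For the other pair 32 probes were used that lay at least 2-fold apart between the strains on all 4 arrays where file and column match. Signed so that the cdc55 strain is positive, the file attached to the cdc55 strain at 20 min minus the file attached to the control strain at 30 min had a median of -1.71 ± 0.09 over them. That the files of the first pair were attached to the wrong samples fits the strain probes too, which the Msn2 genes do not settle, since with the columns' assignment their cdc55 minus control median there was 1.66 ± 0.23.

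For the 135 probes called between the strains in stressed cells, 1 of the 10 splits of the 6 NaCl arrays, the real one, gave as many, and the highest of the others gave 0. Most of the other splits parted the arrays at only 1 of the 3 NaCl times and so broke the pairing by time. In the others a strain difference enters the spread, so their 0 calls are no fair comparison. With 10 splits no share under 0.05 can be reached.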

How the results depend on the processing

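The files as attached and the arrays on which file and column match were alternatives added after the data were seen. A call is taken as reversed only where a value past the threshold changed sign, a definition settled after a first look at the results. Not correcting the background, the deposited value table, either filter on dim probes and a further Aquantile step, which leaves log ratios unchanged by construction, kept all counts of calls within 1.5 times. Over all alternatives 49 counts stayed within 1.5 times and 38 moved. Signal lay far above background on most spots, and whether brightness or the number of arrays limits precision more was not tested. Unless stated, the cause was not tested. Lists based on stress response elements in promoters were not run, for want of a genome sequence.

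With an offset of 0 the count was 220 in stressed cells, 8 unstressed and 1 for the difference in response. Median centring gave 546 in the cdc55 response, 401 in stressed cells, 20 unstressed and 750 for late against early. The Agilent log ratio gave 5 unstressed. The additive strain term gave 2464 for either response, which it forces to be equal, 834 in stressed cells and 1040 for late against early. With no time term 51, 22, 31 and 0 passed for the control response, the cdc55 response, stressed and unstressed cells. An intensity trend gave 484 in stressed cells, 0 unstressed and 952 late. Leaving out a NaCl time gave 33 to 1750 calls in the control response, 13 to 961 in the cdc55 response, 0 to 1012 in stressed cells, 0 to 2 for the difference, 0 to 72 unstressed and 7 late. Leaving out a NaCl time, the Msn2 list medians ranged over 1.91 to 2.09, 1.02 to 1.13, -0.86 to -0.44 and -0.74 to -0.41 for the control response, the cdc55 response, stressed cells and the difference. With an estimated correlation these medians, 1.96, 1.12, -0.64 and -0.48, lost their calls, in a test that also missed the shifted list of the simulation. The 120 named-gene results include many that held no call on all arrays, so they are not the number of calls at risk. Calls lost were 55 without 20 min, 48 with no time term and 23 with an intensity trend. Without 20 min no named gene kept a call in stressed or unstressed cells, where limma called 0 probes.

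The arrays on which file and column match are control at 0 and 20 min and cdc55 at 10 and 30 min. No NaCl time is then shared by the strains, so strain cannot be told apart from time in stressed cells. The control strain keeps only its 20 min array with NaCl. Counts of calls from these arrays therefore cannot show whether the calls hold, and only effect sizes are given. The Msn2 list median was 2.16 in the control response and -0.82 in stressed cells. With the files as attached limma called 0 in every comparison. There the cdc55 response reversed for the lists of Msn2 (-0.12), Hog1-dependent (-0.091), trehalose (-0.25) and ribosome assembly genes (0.33). It reversed for RTC3 (-0.30), CTT1 (-0.41), STL1 (-0.88), ALD3 (-0.31), GPD1 (-0.33), FMP48 (-1.52), INA1 (0.016), HAP4 (0.30), MSN4 (-0.10), LEU2 (-0.15) and ENA1 (-0.44). In stressed cells the strain difference reversed for the lists of Msn2 (0.37), trehalose (0.084), phosphate (0.050), Gcn4 (0.10), sulfur (0.0081) and respiration genes (0.052). It reversed for PRM7 (-1.06), BSC1 (-0.85), YOR338W (-0.25), SPO22 (-0.50), YFL051C (-0.16), ARG1 (0.45), YCL021W-A (0.32), FET3 (0.60) and HXK1 (0.20). ALD3 reversed to 1.52. Unstressed, the respiration (0.11), iron (0.21) and ergosterol lists (0.23) reversed, and late against early the G2 to M list (-0.043).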

Other observations

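No tests beyond the planned ones were made for this part. Of 29 genes of the G1 to S transition 9 fell, 1 rose and 19 did not pass in the control strain, and 10 fell and 1 rose adjusted over the list alone, for example SMC3, a cohesin gene, at -1.69 ± 0.17 (log2, SE). Of 21 genes of the G2 to M transition 4 fell and 17 did not pass, and 4 fell adjusted over the list alone. The medians were -0.46 and -0.54 (camera adjusted p = 6.68e-04 and 5.68e-04), each with adjusted p = 0.554 with an estimated correlation. From 10 to 30 min the B-type cyclin gene CLB2 rose by 1.61 ± 0.31 and CDC20 by 1.37 ± 0.23, in a G2 to M list with 3 higher and 18 not past the test, and 6 higher and 1 lower adjusted over the list alone (median 0.35, camera adjusted p = 0.0377, and adjusted p = 0.834 with an estimated correlation). The 10 histone genes had a median of -0.39 in the control response with 0 past the test in limma, over all probes or adjusted over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.554 with an estimated correlation).

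Of 32 proteasome genes 32 had positive control responses, 4 rose and 28 did not pass, and 14 rose adjusted over the list alone, RPN6 by 1.14 ± 0.24 (median 0.67, camera adjusted p = 5.45e-08, and adjusted p = 0.554 with an estimated correlation). Of 24 chaperone genes known as Hsf1 targets 6 rose and 18 did not pass, and 6 rose adjusted over the list alone, SSA4 by 2.98 ± 0.26. Their median was 0.47 (camera adjusted p = 0.00257, and adjusted p = 0.554 with an estimated correlation), and 0.07 with median centring (camera adjusted p = 0.393). Of 20 oxidative stress genes 3 rose, 1 fell and 16 did not pass, and 5 rose and 1 fell adjusted over the list alone (median 0.29, camera adjusted p = 0.0192, and adjusted p = 0.554 with an estimated correlation). Of 18 genes of PP2A and its regulators 3 rose and 15 did not pass, and 7 rose and 2 fell adjusted over the list alone, PPE1, a phosphatase methylesterase gene, by 1.19 ± 0.19 (median 0.46, camera adjusted p = 0.0292, and adjusted p = 0.554 with an estimated correlation). Of 24 genes of the Hog1 kinase pathway 1 rose, 3 fell and 20 did not pass, and 2 rose and 3 fell adjusted over the list alone (median 0.19, camera adjusted p = 0.405, and adjusted p = 0.763 with an estimated correlation).

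Of 19 iron uptake genes 5 rose, 1 fell and 13 did not pass in the control response, and 6 rose and 2 fell adjusted over the list alone (median 0.10, camera adjusted p = 0.112, and adjusted p = 0.554 with an estimated correlation). From 10 to 30 min FIT1, a cell wall mannoprotein gene, was lower at -3.47 ± 0.23, while the siderophore transporter gene SIT1 rose by 2.78 ± 0.30 and TIS11 by 1.96 ± 0.20. Of 28 pheromone and filamentation genes 3 rose, 2 fell and 23 did not pass in the control response, and 4 rose and 2 fell adjusted over the list alone (median 0.02, camera adjusted p = 0.496, and adjusted p = 0.588 with an estimated correlation). From 10 to 30 min PRM10 was lower at -3.27 ± 0.28, FUS1, a cell fusion gene, at -1.81 ± 0.16 and TEC1 at -1.73 ± 0.16. Of 20 mating type and meiotic genes, markers of another cell type, 3 fell and 17 did not pass in the control response, and 3 rose and 3 fell adjusted over the list alone (median 0.27, mean -0.02, camera adjusted p = 0.405, and adjusted p = 0.554 with an estimated correlation). In stressed cells these 20 genes had a median strain difference of -0.32, with 0 past the test in limma over all probes and 3 lower adjusted over the list alone (camera adjusted p = 0.00382, adjusted p = 0.502 with an estimated correlation, fry adjusted p = 0.0447, the only 1 of 26 lists to pass fry there). Of 20 cell wall genes CWP1 rose by 2.47 ± 0.43 and GSC2 by 1.60 ± 0.30 and 18 did not pass, with 2 higher adjusted over the list alone (median 0.15, camera adjusted p = 0.405, and adjusted p = 0.838 with an estimated correlation).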
